A study of Mus musculus with 12 samples.

How the data were processed

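RNA-seq libraries had been made from liver and white fat (WAT, inguinal by the labels) of male mice aged 52 weeks that were fasted for 12 hours. The mice were wild-type (WT) or labelled knockout (KO) for the microRNA cluster miR-322, miR-503 and miR-351. Per the labels' protocols, total RNA was extracted with TRIZOL and 2 µg of it went into a directional NEBNext kit. The deposited table holds read counts per Ensembl gene, as whole numbers with 1 column per sample, and the authors did not normalise them, as far as the values show. CASAVA 1.8 and HISAT2 are named, with the builds GRCm38 and mm10, per the submitters' processing notes. The counting program, its strand setting and the annotation release are not given in the sources used here. Of the 54532 genes in the table, 54409 were found in GENCODE release M21 (GRCm38), and 53499 of those have the same start and end there. Reads shared between near-identical genes may have been split or dropped by the authors' counting, so Acot1, Cyp4a12b, the Mup and Ugt2b genes and C4a, which have close paralogs, carry that uncertainty. Where genes on opposite strands overlap, their reads cannot be told apart without the strand setting.

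Samples were placed in 4 groups of 3 from their titles (WT_liver, KO_liver, WT_WAT and KO_WAT), and each column was matched to its sample by name. The labels do not say whether the samples of a group are separate animals, so the p-values measure the spread between these samples. Total counts per library lay between 14531438 and 15971178, at which 3 counts in a single library correspond to 0.188 to 0.206 CPM (counts scaled to library totals). For a gene at 0 in a group, the floor was 3 counts over all libraries of the group together. Folds against a floor cover counting error only.

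From the counts, each tissue was fitted by itself in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood F test of genotype), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. All p-values per gene in the text are from this test unless another tool is named. The difference of the genotype effects between the tissues, (KO_WAT minus WT_WAT) minus (KO_liver minus WT_liver), was tested in a fit of all 12 libraries. Log2 fold changes are KO minus WT with their standard errors (SE), and levels are CPM as mean ± SD. 45 gene lists were written before the data were examined, and those with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Within a list, single genes were also counted at an adjusted p under 0.05 adjusted over the list alone. Sites for the 3 microRNA seeds (8mer or 7mer-m8) were searched in the longest annotated 3' UTR of each tested protein-coding gene, and the genes with a site were compared with the rest by camera. All heptamers with sites in at least 50 genes were also ranked by the t statistic of their slope of fold change on site presence, with UTR length and GC share as covariates.

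The genes named in each tissue followed a rule set before the data were examined. It takes the cluster and its neighbours, and up to 8 protein-coding genes per direction with the largest change among those past the threshold, with a mean log2 CPM of at least 1 and groups that do not overlap. It adds up to 3 genes past the threshold per list or seed-site set. Where too few qualify, the next genes by unadjusted p are given as values only. For the difference between tissues it takes the first genes by adjusted p in each direction. Some genes that the rule takes are not reported here. Genes outside the rule were chosen after their values were seen. These are Ugt2b1, C4a, Il13ra1, Gm28730, Ccnd1, Alb, members of a list named because they passed the test over the list alone, members of the female-biased list, and the fat markers given as levels.

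The alternatives set before the data were examined were DESeq2 size factors and upper quartile factors, no filter and a stricter one (at least 1 CPM in at least 3 libraries), DESeq2 1.42.0, limma voom, no robust step, a fit of all 4 groups, the replicate number as a block, an adjusted p under 0.1, a fold of at least 2, and leaving out each library in turn. For lists and seed sites they also included fry, an estimated correlation, 8mer sites alone, the shortest UTR, and UTR length and GC share as covariates. Chosen after seeing the data were the removal of each library's trend on GC share and length of the longest transcript (lowess offsets), fits without the 2 fat libraries highest in Alb, log2 Alb CPM as a covariate, the first 2 of these together, DESeq2 without its filter on the mean count, and the camera test of the lists on the difference between tissues.

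The fits were tested on simulated counts with planted changes, drawn from the means, dispersions and library sizes of the real libraries. In the simulated liver comparison (13477 genes), 67.7% of the genes changed 2-fold and 93.8% of those changed 4-fold were called, and 4.91% of the calls were not planted. In the simulated fat comparison (15864 genes) the shares were 43.2% and 70.5%, with 15.0% not planted. For the difference between tissues (16865 genes) they were 12.2% and 58.8%, with 14.8% not planted. A list lowered by 0.5 on the log2 scale and a miR-322 site set raised by 0.2 were recovered in both tissues, the heptamer at rank 1. For these, genes were drawn independently of each other and without a trend on GC share. Recovery therefore does not show how the tests behave where genes move together, as the fatty acid oxidation list did in liver (estimated correlation 0.260). No sample and no count column was left out of the tests unless an alternative says so.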

Results

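The deposited counts compare liver and fat (inguinal, by the labels) of 52-week-old male mice labelled knockout (KO) for the microRNA cluster miR-322, miR-503 and miR-351 on the X chromosome with those of wild-type (WT) mice, with 3 libraries per tissue and genotype. Libraries held 14531438 to 15971178 counts and 19295 to 22963 detected genes. Levels below are mean CPM ± SD (n = 3 per group), and log2 fold changes are KO minus WT ± SE. Each pair of libraries of a group differed by more than counting noise (chi-square per degree of freedom of 9.83 to 77), so no library was taken for a copy of another. The labels do not say whether the libraries of a group are from separate animals, and each was counted as 1 sample.

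The first question was what remained of the cluster itself. The microRNA genes Mir503 and Mir322 (GRCm38, X chromosome, minus strand, 53053984 to 53054054 and 53054255 to 53054349) had 0 counts in all 6 KO libraries, as did the neighbouring Gm28730 (53051194 to 53053159). In WT fat, Mir503 had 48 counts over the group (1.03 ± 0.316 CPM) and Mir322 had 37 (0.806 ± 0.207 CPM). Against a floor of 3 counts over the group, KO fat was at least 16-fold lower for Mir503, at least 12.3-fold lower for Mir322 and at least 5.66-fold lower for Gm28730. KO liver was at least 5.28-fold lower for Mir503 and at least 3.96-fold lower for Gm28730, while Mir322, with 3 counts over WT liver, gave no fold.

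Mir351 (53053255 to 53053353), which lies between Gm28730 and Mir503, had more counts in KO than in WT libraries in both tissues. It had 41 against 9 counts in liver (log2 fold change 2.18 ± 0.60, adjusted p = 0.213) and 146 against 33 in fat (2.16 ± 0.38, adjusted p = 0.428, and 0.0210 with DESeq2). The long noncoding gene C430049B03Rik (53055046 to 53057190), next to Mir322, rose in KO liver from 0.134 ± 0.0694 to 4.57 ± 0.114 CPM (log2 fold change 5.04 ± 0.42, adjusted p = 0.000356). In fat it had 1.20 ± 0.756 CPM in WT and 24.3 ± 6.57 CPM in KO libraries (4.34 ± 0.42, adjusted p = 0.0708, and 3.65e-27 with DESeq2). Of the neighbouring protein-coding genes, none passed the threshold in either tissue. Hprt, a purine salvage enzyme used as a reference gene, had log2 fold changes of 0.12 in liver and -0.17 in fat, Phf6 0.23 and -0.12, Mospd1 0.46 and -0.37, Fam122b -0.03 and -0.63, and Gpc3 -0.17 and 0.09. These counts come from long-RNA libraries, and mature microRNAs were not analysed here.

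**Figure D1:**
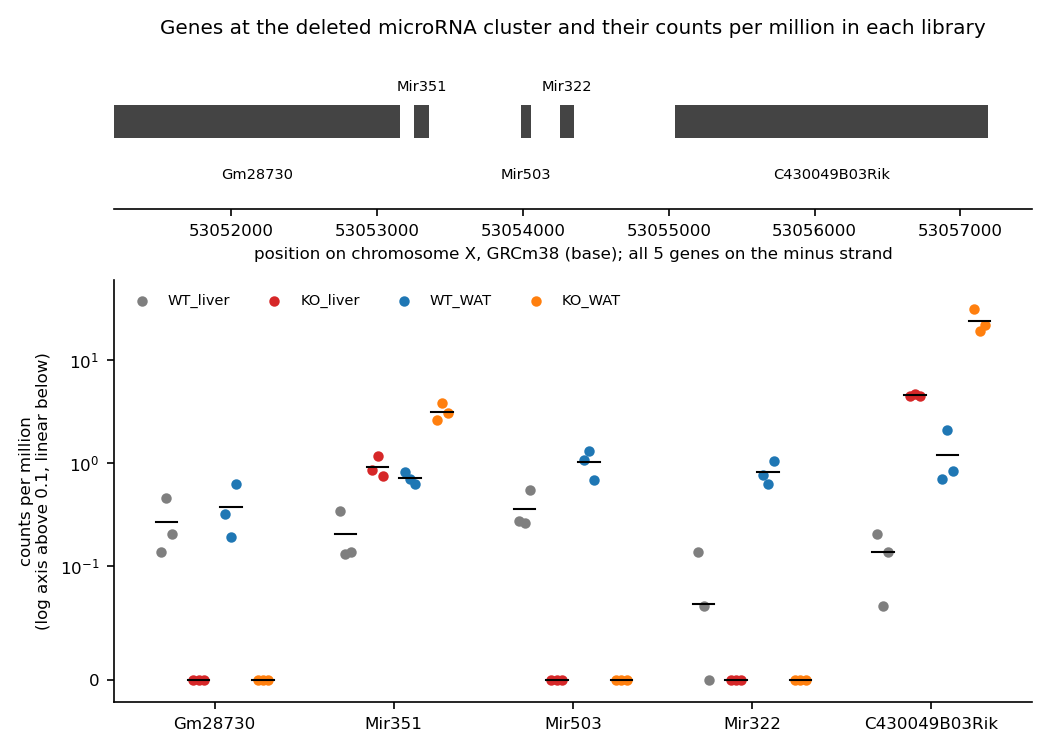
The upper panel maps the 5 genes at the cluster to scale on the X chromosome (GRCm38), and the lower panel plots CPM (log axis above 0.1, linear below) for each library as points and each group mean as a bar. All 6 KO libraries sit at 0 for Gm28730, Mir503 and Mir322, and above every WT library of their tissue for Mir351 and C430049B03Rik.

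The liver comparison asked which genes differ between KO and WT libraries. Acot1, which releases fatty acids from long-chain acyl-CoA (chromosome 12, 84009490 to 84018371), fell from 138 ± 7.50 to 45.4 ± 9.86 CPM in KO liver (log2 fold change -1.58 ± 0.14, adjusted p = 0.00116). Cyp4a12b, a fatty acid hydroxylase expressed mainly in male liver, rose from 41.4 ± 4.78 to 79.8 ± 6.34 CPM (0.98 ± 0.11, adjusted p = 0.00499). Both have close paralogs that share sequence. Spp1, which encodes osteopontin, rose from 29.2 ± 3.60 to 52.6 ± 7.26 CPM (0.88 ± 0.13, adjusted p = 0.0275). Nr1i3, the nuclear receptor CAR that controls xenobiotic metabolism, fell from 64.7 ± 2.07 to 39.8 ± 3.27 CPM (-0.67 ± 0.10, adjusted p = 0.0280).

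Of 13529 genes tested in liver, 21 passed the threshold, 14 higher and 7 lower in KO, and 19 of them encode proteins. Besides those above, Acpp (1.22), the magnesium transporter Slc41a2 (1.14), Mup14 (0.95), the complement gene C4a (0.89), Hal of histidine breakdown (0.68), Rarres1 (0.68), the interleukin receptor chain Il13ra1 (0.67), Antxr2 (0.67), Ugt2b35 (0.66) and Ugt2b1 (0.65) rose, as did Gm14403 (0.92). Fam131c (-2.08), the lysosomal transporter Slc15a4 (-1.08), the phosphatase Alpl (-0.81), Lgals4 (-0.69) and Agmat (-0.60) fell. Mup14, C4a, Gm14403 and the Ugt2b genes also have close paralogs. Crat, a mitochondrial carnitine acetyltransferase, had a log2 fold change of -0.91 ± 0.15 (adjusted p = 0.0562). At an unadjusted p under 0.05 there were 1652 genes, where 676.5 would be reached by chance, and the groups did not overlap for 18.8% of the tested genes, where chance gives 10%.

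Fold changes in liver ran with the GC share of the transcripts (rho = -0.435 across genes, which are not independent replicates). With that trend and the length trend of each library removed, 1087 genes had an unadjusted p under 0.05, in place of 1652. Of the 21 calls, 4 were kept. These were C430049B03Rik, Acot1 (-1.63 ± 0.13), Cyp4a12b (0.92 ± 0.11) and C4a (1.01 ± 0.13). The other 17 kept their directions and had adjusted p between 0.0982 and 0.201. Of these 17, 16 had a smaller absolute log2 fold change after removal, such as Agmat (-0.60 to -0.42) and Ugt2b1 (0.65 to 0.49). Rarres1 went the other way (0.68 to 0.72). Among the 16, Hal changed least (0.68 to 0.66) and Fam131c most (-2.08 to -1.78). The median absolute log2 fold change of the 17 was 0.66 in place of 0.69, at a median SE of 0.117 in place of 0.118. These medians fall on different genes before and after, so they do not give the change per gene. The number of calls was 8 without KO_liver1, 34 without KO_liver3, 12 without WT_liver1, 8 without WT_liver2 and 5 without WT_liver3, and C430049B03Rik, Acot1 and Cyp4a12b were called in 6 of 6 such fits.

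**Figure D2:**
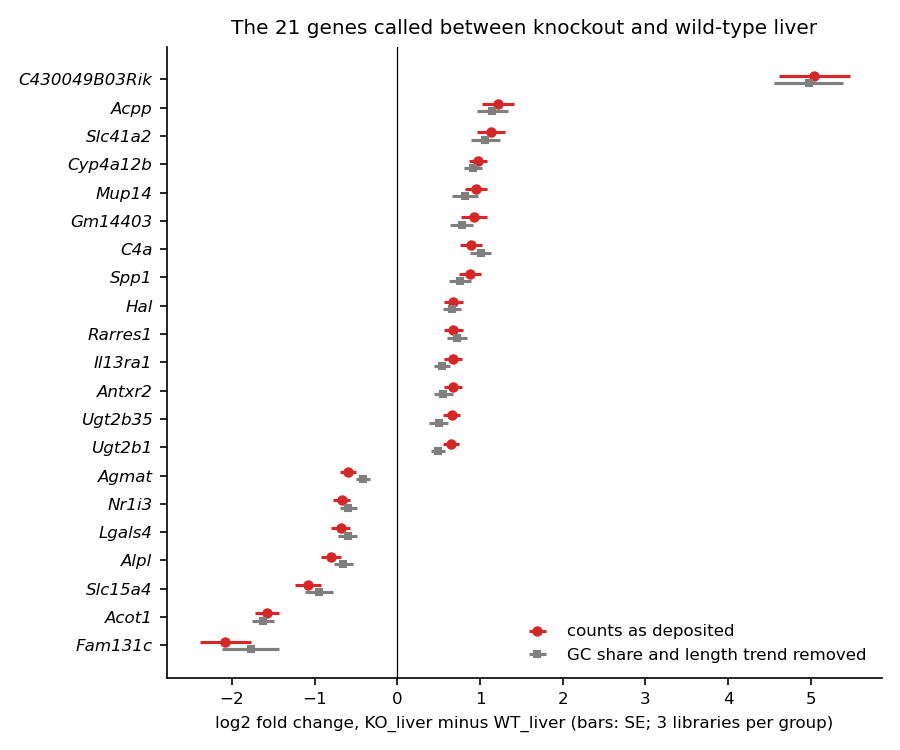
Log2 fold changes (KO_liver minus WT_liver) of the 21 genes past the threshold, as points with SE bars from 3 libraries per group, from the counts as deposited and with the GC share and length trend of each library removed. Acot1 sits at -1.58 and -1.63, and C430049B03Rik at 5.04 and 4.97.

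Among the lists of genes tested in liver, those of fat burning were lower in KO. All 30 measured genes of fatty acid oxidation and ketogenesis had lower values in KO (median -0.28), and camera with a preset correlation of 0.01 called the list lower (adjusted p = 2.84e-10, and adjusted p = 0.677 with an estimated correlation). Acot1 alone passed over all genes, and 10 genes were lower with p adjusted over the list alone. Among the latter, the fasting hormone Fgf21 went from 6.68 ± 0.227 to 1.89 ± 1.34 CPM (-1.79 ± 0.40), and the acyl-CoA dehydrogenase Acadm and the carnitine transferase Cpt2 had log2 fold changes of -0.36 ± 0.10 and -0.31 ± 0.10. The lipid droplet and uptake list was also called lower (adjusted p = 0.000796, and adjusted p = 0.702 with an estimated correlation), with 21 of 24 genes lower and a median of -0.34. No member passed over all genes, while 7 were lower and 1 higher adjusted over the list alone. The droplet coat genes Plin2 (-0.55 ± 0.11) and Plin5 (-0.84 ± 0.21) and the lipase inhibitor G0s2 (-0.86 ± 0.24) were among the 7, and the lipoprotein lipase Lpl (0.77 ± 0.21) was the 1. The lipoprotein list was called lower (adjusted p = 0.0494, and adjusted p = 0.677 with an estimated correlation), with 16 of 20 genes lower and 0 past the threshold over all genes or adjusted over the list alone. Apoe, the most changed of these by p, had -0.55 ± 0.15 (16086 ± 1678 to 10839 ± 2401 CPM).

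The acute phase list was called higher in KO liver (adjusted p = 2.48e-07, and adjusted p = 0.677 with an estimated correlation), with 20 of 23 genes higher and a median of 0.38. 0 of them passed over all genes and 13 were higher adjusted over the list alone, among them Apcs (0.86 ± 0.15), Orm1 (0.86 ± 0.16), the iron-siderophore binder Lcn2 (1.79 ± 0.40) and the fibrinogen gene Fgb (0.40 ± 0.10). Genes known for higher expression in male liver were called higher (adjusted p = 6.05e-06, and adjusted p = 0.702 with an estimated correlation), with 18 of 20 higher and a median of 0.54. Cyp4a12b passed over all genes, and 2 adjusted over the list alone, the other being the urinary protein gene Mup3 (0.50 ± 0.10). The mitochondrially encoded genes were called higher (adjusted p = 0.000703, and adjusted p = 0.687 with an estimated correlation), with 11 of 13 higher, 0 past the threshold over all genes and 4 adjusted over the list alone, such as mt-Nd1 (0.44 ± 0.10) and mt-Co1 (0.36 ± 0.09). They took 6.52% to 7.35% of the counts in KO and 5.55% to 5.83% in WT liver libraries. The cholangiocyte markers were called higher (adjusted p = 0.0435, and adjusted p = 0.677 with an estimated correlation), with 9 of 12 higher, Spp1 past the threshold over all genes, and Spp1 and the epithelial cadherin gene Cdh1 (1.15 ± 0.30) adjusted over the list alone. Spp1 is also on the macrophage and inflammation list, which camera did not call (adjusted p = 0.216), with 20 of 28 higher. With the fry test, no liver list passed (lowest adjusted p = 0.188). Of 10 ways to split the 6 liver libraries into equal groups, 6, the real one included, gave at least 7 lists. Chance is therefore not excluded for the number of liver lists. The calls of fatty acid oxidation, acute phase and male-biased genes held without each single library and with the GC share and length trend removed. Of the others, lipid droplet genes were not called without KO_liver2 (adjusted p = 0.0922), cholangiocyte markers without KO_liver3 (0.0556) or WT_liver3 (0.138), mitochondrially encoded genes without WT_liver1 (0.0643) or with the trend removed (0.257), and lipoprotein genes without KO_liver1 (0.118), KO_liver2 (0.0922), WT_liver2 (0.0987) or WT_liver3 (0.160) or with the trend removed (0.110).

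A further question was whether messages with binding sites for the 3 microRNAs moved as a set. Genes whose 3' UTR holds a site did not differ from the rest by camera in either tissue for any of the 3 seeds (0 of 3 sets per tissue). Counts at Mir351 remained in the KO libraries, so the miR-351 set need not test a loss of that microRNA. In liver, 2946 of 11852 genes held a miR-322 site (TGCTGCT), 585 a miR-503 site (CGCTGCT) and 1899 a miR-351 site (CTCAGGG). Their medians differed from the other genes by 0.02, -0.01 and -0.03 (each with an adjusted p of 0.619 by limma camera). In fat the differences were -0.04, 0.01 and 0.02 (adjusted p of 0.468, 0.631 and 0.631 by limma camera), over 3361, 674 and 2173 of 13654 genes. By the t statistic of the slope of fold change on site presence, the 3 heptamers ranked 9553, 8414 and 6255 of 16106 from the highest in liver. In fat they ranked 1751, 12161 and 560 of 16176. Of the called liver genes, Slc15a4 and Slc41a2 hold a miR-322 site, and Slc15a4 and Antxr2 a miR-351 site. Among the listed targets of the miR-15/16 family, to which miR-322 belongs by its seed, the cyclin gene Ccnd1 had a lower level in KO liver (-1.18 ± 0.23, adjusted p = 0.0897, and 0.0101 adjusted over the list alone), and the 34 measured genes were 17 higher and 17 lower.

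The fat comparison asked the same of white fat, labelled inguinal, and there the genes of fat synthesis stood out. Of 22 measured genes of fatty acid and triglyceride synthesis, 19 were higher in KO fat, with a median of 0.76, and camera called the list higher (adjusted p = 1.25e-08, and adjusted p = 0.546 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA from citrate (chromosome 11, 100476353 to 100528000), had 222 ± 14 CPM in WT and 686 ± 132 CPM in KO fat (1.65 ± 0.18, adjusted p = 0.0708, and 7.67e-16 with DESeq2). The fatty acid synthase gene Fasn had 2268 ± 425 and 6742 ± 2077 CPM (1.60 ± 0.28, adjusted p = 0.428, and 4.77e-08 with DESeq2). 0 of the list passed over all genes and 9 were higher adjusted over the list alone, among them also Acss2 (1.24 ± 0.22), the elongase Elovl6 (1.02 ± 0.23), Agpat2 (0.95 ± 0.21) and the lipogenic regulator Srebf1 (0.77 ± 0.20).

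Of 15919 genes tested in fat, 0 passed with edgeR, 1216 had an unadjusted p under 0.05 (695 higher and 521 lower, where 796 in all would be reached by chance), and the groups did not overlap for 14.9%, where chance gives 10%. With the GC share and length trend of each library removed, 813 genes had an unadjusted p under 0.05, near the 796 of chance. DESeq2 called 43 genes (34 higher and 9 lower) and limma voom 0, and edgeR without a filter called 29. Beyond fat synthesis, the genes with the smallest p included the citrate carrier Slc25a1 (1.02 ± 0.18), the parathyroid hormone receptor Pth1r (1.23 ± 0.18), the prostaglandin synthase Ptges (0.94 ± 0.15), Slpi (0.88 ± 0.15) and Ano8 (0.75 ± 0.13) among those higher. Those lower were the growth factor genes Btc (-0.84 ± 0.12), Kitl (-0.66 ± 0.13) and Pdgfd (-0.69 ± 0.13), with Plekhg1 (-0.75 ± 0.15), Senp7 (-0.60 ± 0.14), Ranbp9 (-0.54 ± 0.12), Ugcg (-0.53 ± 0.11) and Prex2 (-0.50 ± 0.11). Their adjusted p lay between 0.291 and 0.601 with edgeR. Fold changes in fat ran with the GC share in the other direction from liver (rho = 0.475 across genes), and with the trend removed Acly had 1.59 ± 0.17 and Fasn 1.40 ± 0.26, while Kitl had -0.41 ± 0.10, Senp7 -0.36 ± 0.13 and Prex2 -0.24 ± 0.09.

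Of the lists tested in fat, 14 were called by camera, and none of the 14 with an estimated correlation or by fry (lowest adjusted p = 0.546 and 0.270). Of 10 ways to split the 6 fat libraries into equal groups, 6, the real one included, gave at least 14 lists. Chance is therefore not excluded for the number of fat lists. T and NK cell markers were called lower (adjusted p = 1.01e-07, and adjusted p = 0.546 with an estimated correlation), with 17 of 17 lower and a median of -1.02, such as Cd3e (-1.37 ± 0.46). B cell and lymph node markers were not called by camera (adjusted p = 0.0767), with 18 of 20 lower and a median of -0.65. Whether these values follow the lymphoid content of the samples was not tested. The antigen presentation list was called lower (adjusted p = 0.00241, and adjusted p = 0.685 with an estimated correlation), with 11 of 12 lower, among them Cd86 (-0.70 ± 0.28). The unfolded protein response list was called lower (adjusted p = 0.00241, and adjusted p = 0.685 with an estimated correlation), with 23 of 26 lower, among them the chaperone Hspa5 (-0.43 ± 0.18). All 36 nuclear genes of oxidative phosphorylation were higher, with a median of 0.20 (adjusted p = 9.64e-07, and adjusted p = 0.685 with an estimated correlation), for example Cox5b (0.42 ± 0.14) and Cox6a1 (0.40 ± 0.13). With the GC share and length trend removed, Cox5b had 0.38 ± 0.12 and Cox6a1 0.04 ± 0.14. The adipocyte identity list was called higher (adjusted p = 0.00887, and adjusted p = 0.725 with an estimated correlation), with 19 of 26 higher, and Gpd1, which makes glycerol 3-phosphate (0.98 ± 0.22), passed adjusted over the list alone. With the trend removed Gpd1 had 0.75 ± 0.22, while Cebpb, also on the list, went from 0.60 ± 0.18 to 0.10 ± 0.13. The cholesterol synthesis list was called higher (adjusted p = 0.00910, and adjusted p = 0.685 with an estimated correlation), with 18 of 23 higher and Pmvk (0.93 ± 0.20) past the threshold adjusted over the list alone. Over all genes, 0 members of any list passed.

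The other 7 lists called higher in fat were of liver or epithelial genes. They were the acute phase list (adjusted p = 0.00373, and adjusted p = 0.546 with an estimated correlation; 20 of 23 higher), keratinocyte markers (0.00689, and adjusted p = 0.546 with an estimated correlation; 5 of 6) and hepatocyte markers (0.00887, and adjusted p = 0.725 with an estimated correlation; 20 of 22). The lipoprotein list (0.0139; 15 of 18), male-biased liver genes (0.0165; 14 of 18) and bile acid genes (0.0435; 12 of 15) each had adjusted p = 0.725 with an estimated correlation, and cholangiocyte markers (0.0435; 7 of 7) had adjusted p = 0.546 with an estimated correlation. Examples are Saa1 (3.26 ± 0.79, from 0.0881 to 0.889 CPM), Krt14 (1.53 ± 0.55), the lipase regulator Angptl8 (1.23 ± 0.29) and Krt19 (0.53 ± 0.14), the last 2 past the threshold adjusted over the list alone. Krt19 is also on the list of mesothelial markers and lay between 35.9 and 62.1 CPM in the fat libraries, against 1.13 CPM on average in liver. Hepatocyte transcripts were unevenly spread over the fat libraries. The median level of 22 hepatocyte markers was 2.90% of that in liver in KO_WAT1, 2.65% in WT_WAT1, 1.06% in KO_WAT3, 0.386% in KO_WAT2, 0.240% in WT_WAT2 and 0.113% in WT_WAT3, and Alb ran from 76.8 to 1977 CPM. Fat synthesis, T and NK cell markers and oxidative phosphorylation were called without each single library. Without KO_WAT1, 6 of the lists were called, these 3 with antigen presentation, unfolded protein response and adipocyte identity, and the liver and epithelial lists were not (hepatocyte markers 0.416, acute phase 0.154, keratinocyte markers 0.248, lipoprotein genes 0.263, male-biased genes 0.326, bile acid genes 0.583 and cholangiocyte markers 0.0904), nor was cholesterol synthesis (0.248). Without WT_WAT2 or WT_WAT3, hepatocyte markers (adjusted p = 0.105 and 0.476), lipoprotein genes (0.184 and 0.141), male-biased genes (0.105 and 0.598) and bile acid genes (0.293 and 0.621) were not called. Antigen presentation (0.0569 and 0.0686) and adipocyte identity (0.166 and 0.235) were not called without KO_WAT2 or WT_WAT3, cholangiocyte markers (0.214) without KO_WAT2, and unfolded protein response (0.0646) and cholesterol synthesis (0.255) without WT_WAT1. Without both libraries highest in Alb, KO_WAT1 and WT_WAT1, the fat synthesis list and the hepatocyte markers each had an adjusted p of 7.71e-07, while cholesterol synthesis (0.630), keratinocyte (0.223) and cholangiocyte markers (0.151) were not called, and with log2 Alb as a covariate hepatocyte markers (0.832), lipoprotein (0.730), male-biased (0.832) and bile acid genes (0.873) were not.

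**Figure D3:**
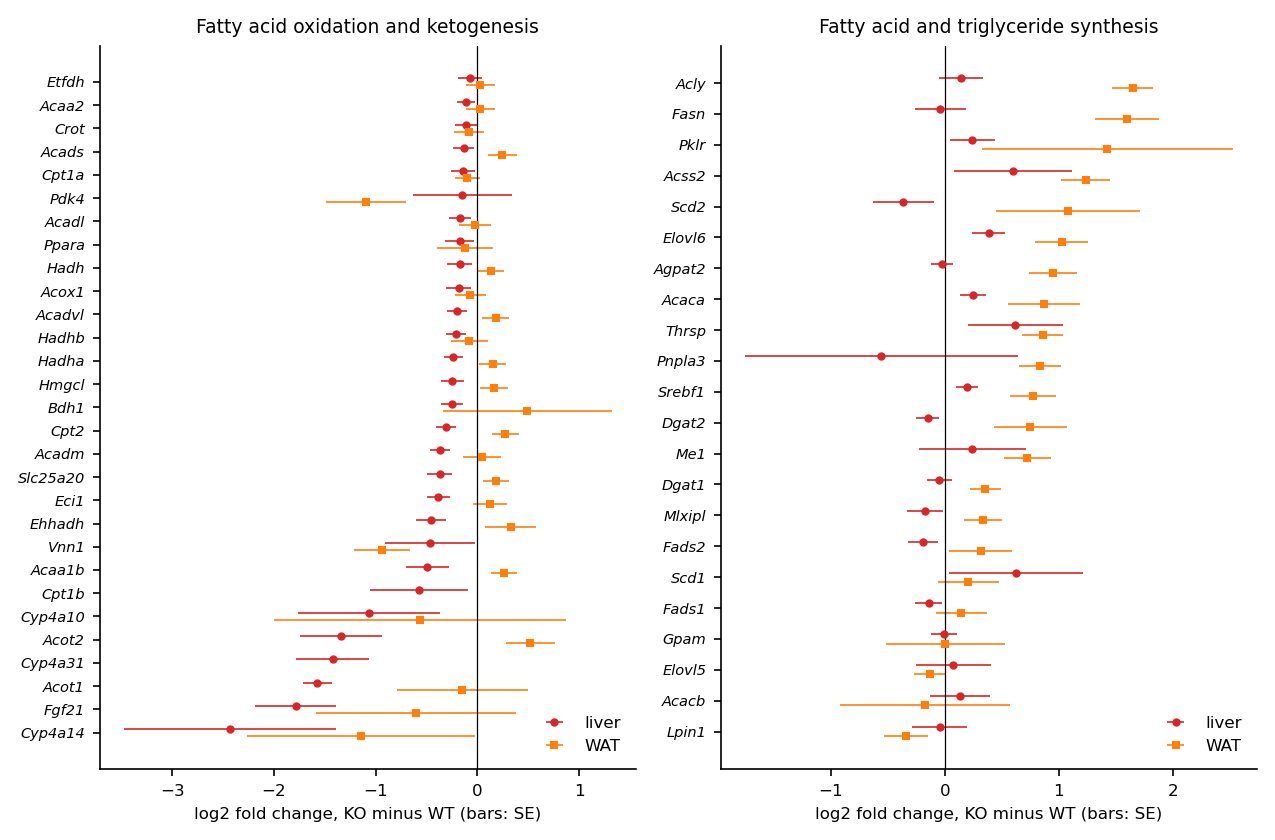
Log2 fold changes (KO minus WT) with SE bars for measured genes of 2 lists in liver (circles) and fat (squares), from 3 libraries per group and tissue. In liver all oxidation genes drawn sit below 0, and in fat 19 of 22 synthesis genes sit above 0.

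Whether the genotype acts differently on the tissues was tested as the difference of the log2 fold changes (fat minus liver). The electron transfer flavoprotein gene Etfb (-0.51 in liver and 0.98 in fat, difference 1.47 ± 0.24), Pth1r (-0.30 and 1.23, difference 1.51 ± 0.26) and Gpd1 (-0.47 and 0.98, difference 1.43 ± 0.26) had the smallest p among genes higher in fat, with C1qtnf12 (difference 1.32 ± 0.25) and Hcfc1r1 (0.85 ± 0.16). In the other direction stood Btc (0.67 and -0.84, difference -1.53 ± 0.27), Nxt2 (0.44 and -0.54, difference -0.99 ± 0.17), Lrrc49 (-2.96 ± 0.54), Rlf (0.48 in liver and -0.50 in fat) and Antxr2 (-0.89 ± 0.17). Each had an adjusted p of 0.159, and of 16857 genes tested 0 passed with edgeR, with 2255 at an unadjusted p under 0.05 (842.9 by chance) and 188 called by DESeq2. With the GC share and length trend removed, 1144 had an unadjusted p under 0.05 with edgeR. The count of genes past the threshold was 25 without KO_WAT1, 34 without WT_WAT1 and 1 without WT_liver1. Without KO_WAT1 and WT_WAT1, the fat libraries highest in Alb, it was 713 (515 higher in fat and 198 lower), and 69 when the GC share and length trend was removed as well.

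Of 12706 genes tested in both tissues, 0 passed in both with edgeR and 0 with DESeq2, whose filter on the mean count left 10057 of them with an adjusted p in both. Without that filter DESeq2 called 1 gene in both tissues, C430049B03Rik, higher in KO (adjusted p of 9.49e-10 in liver and 7.09e-27 in fat). At an unadjusted p under 0.05, 22 genes had the same direction in both tissues (61.3 for independent lists), 16 higher and 6 lower, and 173 had opposite directions (62.0 for independent lists). Across these genes, which are not independent replicates, the fold changes of the tissues had r = -0.120 and rho = -0.257. With the GC share and length trend removed, rho was -0.0254, with 54 opposite genes (25.8 for independent lists) and 22 with the same direction (26.0).

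**Figure D4:**
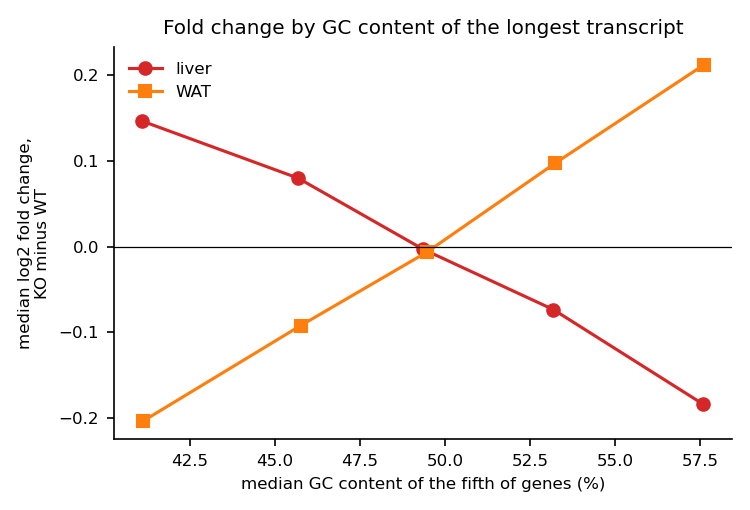
Median log2 fold change (KO minus WT) against the median GC content of the longest transcripts (%), with the tested genes placed in 5 equal classes by GC content, for liver (circles) and fat (squares). The medians go from 0.15 to -0.18 in liver and from -0.20 to 0.21 in fat.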

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

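The lists on the difference between tissues, the removal of the GC share and length trend, the fits without the fat libraries highest in Alb, the Alb covariate and the count of splits in either direction were chosen only after the results were seen.

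For 7 lists the genotype effect differed between fat and liver by camera with the preset correlation, and that difference between groups marked them out. Fatty acid oxidation had a median difference of 0.37 (adjusted p = 0.00147) and fatty acid and triglyceride synthesis one of 0.52 (adjusted p = 0.00147). The lipid droplet list had 0.48, the lipoprotein list 0.65, oxidative phosphorylation 0.19 and T and NK cell markers -0.86, each with an adjusted p of 0.0150. B cell and lymph node markers had -1.16 (adjusted p = 0.0387). With an estimated correlation 0 of the 7 passed (adjusted p between 0.926 and 0.938), and oxidative phosphorylation was not called without KO_WAT1 and WT_WAT1 (adjusted p = 0.132). In 36 of the 40 splits within tissues at least 7 lists were called (highest other 22), so chance is not excluded for this number. For the genes of the difference between tissues, 40 of 40 splits gave at least the real count of 0, as they must. The highest other split gave 181, and the cause of that count was not tested. Of the genes called in both tissues, all 100 splits gave at least the real count of 0 (highest other 0), as they must, so this says nothing about chance.

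Within a tissue, 10 splits cannot give a share under 0.05. In liver, 1 split of 10 gave at least the 21 genes of the real one, which was the real one itself (highest other 2), and 6 of 10 gave at least the 7 lists (highest other 15). In fat, 10 of 10 gave at least the real 0 genes (highest other 25) and 6 of 10 at least the 14 lists (highest other 16). Splits that mix the genotypes thus gave as many lists, so chance is not excluded for the number of lists in either tissue. For the seed-site sets, 10 of 10 splits gave at least the real 0 in each tissue (highest other 0). A real count of 0 is met by every split. The fat split with 25 genes sets the 3 libraries highest in Alb (KO_WAT1, KO_WAT3 and WT_WAT1) against the rest, which points to a structure of the samples other than genotype. The split of KO_WAT1, WT_WAT2 and WT_WAT3 against the rest gave 2532 genes at an unadjusted p under 0.05, against 1216 for the genotypes.

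Fold changes in liver and fat ran opposite ways across genes (rho = -0.257), and 3 of 100 splits within tissues, the real one included, gave a value as negative, the most negative other being -0.337. In either direction 5 of 100 gave a value as large in size (highest other 0.337). Among these 5 was the real split with the genotype labels exchanged in a single tissue (rho = 0.257). Other splits were also drawn with such a mirror image, so the 100 are not all distinct groupings. The share in either direction therefore does not decide the question, and chance is not excluded. Only for the negative direction taken alone did the share, 3 of 100, lie under 0.05. Liver RNA in the fat libraries is argued against as the source, since rho was -0.224 with log2 Alb as a covariate in fat, with which hepatocyte markers were not called (adjusted p = 0.832). A candidate explanation is a library trend on GC share and transcript length, since its removal brought rho to -0.0254, while rho with GC share was -0.436 to -0.0800 in the KO and 0.213 to 0.294 in the WT liver libraries. In fat these values were -0.226, 0.402 and 0.525 for KO and -0.0213, -0.268 and -0.409 for WT, so KO_WAT1 sat with the WT libraries. An effect of the genotype that itself follows GC share stays open and untested, because the trend moves with genotype in liver.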

How the results depend on the processing

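Removal of the GC share and length trend, the fits without KO_WAT1 and WT_WAT1 (the fat libraries highest in Alb), the Alb covariate, DESeq2 without its filter on the mean count and the list test of the difference between tissues were chosen only after the results were seen. For the number of genes called in liver (21), no filter gave 378, DESeq2 152 (20 shared), limma voom 3, no robust step 3, all 4 groups in one fit 1, removal of the GC share and length trend 4, an adjusted p under 0.1 46 and a fold of at least 2 gave 6. Leaving out 1 library gave 5 to 34. For the genes in fat (0), no filter gave 29, DESeq2 43, all 4 groups in one fit 3 and an adjusted p under 0.1 gave 2, with 0 to 1 on leaving out 1 library. For the difference between tissues (0 genes), no filter gave 21, DESeq2 188, leaving out the fat libraries highest in Alb 713, that with the trend removed 69, and leaving out 1 library 0 to 34. For genes called in both tissues (0), an adjusted p under 0.1 gave 1, DESeq2 without its filter on the mean count 1 and leaving out 1 library 0 to 1. An estimated correlation gave 0 lists in liver, 0 in fat and 0 for the difference between tissues, and fry 0 in liver and 0 in fat. Leaving out 1 library gave 6 to 10 lists in liver (7) and 6 to 19 in fat (14). Without the fat libraries highest in Alb and with the trend removed, 23 lists were called in fat. For the difference between tissues (7 lists), leaving out those libraries gave 15, and 14 with the trend removed too. Except where the limit on adjusted p or fold was itself changed, the cause of these changes was not tested. The seed-site sets stayed at 0 under every alternative run.

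Of the values for single named genes, 439 in liver, 917 in fat and 161 for the difference between tissues kept direction and side of the threshold, 125 in liver lost the threshold, and 35 in liver, 33 in fat and 39 for the difference between tissues gained it. Another 5 in liver and 12 in fat changed sign, among them values of Hprt, Gpc3, Fam122b and Phf6, none past the threshold before or after (lowest adjusted p after = 0.695). For named lists, 24 values in liver and 59 in fat lost the threshold, and bile acid genes in fat changed direction with the Alb covariate (adjusted p = 0.873). The labels do not say whether the replicate numbers pair the samples. Residuals of libraries with the same number had r of -0.0666 to 0.0816 within liver, 0.0608 to 0.160 within fat and -0.0388 to 0.0730 between the tissues. These values showed no clear pairing, but they cannot exclude it, since samples of 1 mouse need not share residuals. As a block, the number gave 28 genes (17 shared) and 9 lists in liver, 0 genes and 19 lists in fat, 0 seed-site sets, and 0 genes for the difference between tissues. With 3 counts over a group as the floor, depth limits what can be said of Mir322 and Gm28730 in liver.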

Other observations

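The levels of fat markers, the female-biased genes singled out, and all tests of the liver transcripts in fat and of the cluster were chosen only after the results were seen, while the lists were set beforehand.

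The fat libraries carried clear levels of mesothelial genes and almost none of the thermogenic gene Ucp1. Msln, a mesothelial surface protein, lay between 70.8 and 108 CPM in the 6 fat libraries (2.20 CPM on average in liver), Upk3b between 155 and 254 CPM (3.33 in liver), and the transcription factor Wt1 between 20.2 and 39.9 CPM (1.30 in liver). The list of mesothelial and epididymal fat markers was not called between genotypes in fat (adjusted p = 0.118, and 0.0349 without KO_WAT3; 6 of 9 higher). These genes are known from mesothelium and from epididymal fat, so their levels put the inguinal label of all 6 libraries in doubt, and the depot was not tested. Ucp1, the uncoupling protein of brown fat, lay between 0 and 0.138 CPM and Cidea between 0.697 and 2.56 CPM, while Prdm16 lay between 5.57 and 9.96 CPM and Ebf2 between 35.0 and 57.2 CPM. The thermogenic list was not called (adjusted p = 0.310; 11 of 18 higher). The epithelial gene Epcam was at 5.75 CPM in KO_WAT2 and at most 0.272 CPM in the other fat libraries, and the B cell gene Ms4a1 ran from 1.85 CPM to 20.7 CPM, the latter in WT_WAT2.

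Genes known for higher expression in female liver had a median log2 fold change of -1.04 in KO liver, with 10 of 13 lower, which camera did not call (adjusted p = 0.0529, and adjusted p = 0.808 with an estimated correlation). It was called lower without KO_liver1 (0.0466), KO_liver3 (0.00127), WT_liver1 (0.000129) or WT_liver3 (0.0397), with the stricter filter (0.0189), the replicate block (0.0440) or the GC share and length trend removed (0.00991). It was not called without KO_liver2 (0.475) or WT_liver2 (0.522), with DESeq2 size factors (0.0512) or by fry (0.681). Cyp4a14, a fatty acid hydroxylase, had -2.43 ± 1.04, the peroxisomal transporter gene Abcd2 -1.38 ± 0.45 and the steroid hydroxylase gene Cyp17a1 -1.18. The xenobiotic metabolism list was not called either (adjusted p = 0.972), with 14 of 27 higher. Nr1i3 and Ugt2b35 passed over all genes, and 4 members adjusted over the list alone, the others being Cyp3a13 (0.58 ± 0.11) and Por (-0.40 ± 0.10), which passes electrons to cytochrome P450 enzymes.

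Hepatocyte transcripts appeared in the fat libraries, most in KO_WAT1 and WT_WAT1. The genotype is not excluded as a source. The lowest KO library had 0.146 times the share of the highest WT library, but this overlap rests on WT_WAT1. Without KO_WAT1 and WT_WAT1 the shares were 0.386% and 1.06% in KO and 0.240% and 0.113% in WT. Camera with the preset correlation then called the hepatocyte markers higher in KO (adjusted p = 7.71e-07). The markers move together (estimated correlation 0.875 over all fat libraries), so this p-value treats 1 share per library as many genes and does not decide the question. RNA from liver may be the source, since 20 of 22 markers in each of these libraries lay within 2-fold of the library's median share, with Alb at 1977 and 1863 CPM. Whether it entered at dissection, extraction or library preparation was not tested.

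Counts at Mir351 and C430049B03Rik were higher in KO libraries while Mir503 and Mir322 had 0. Reads from annotated transcripts of other genes are argued against, since 0 of the 1673 31-base stretches of the 2 genes (69 and 1604) occur in such transcripts, while unannotated places in the genome and inserted sequence were not searched. As far as the reads come from the locus, loss of the whole annotated cluster is argued against, since the lowest Mir351 count of the 6 KO libraries was 11. A transcript that starts at C430049B03Rik and runs across an altered locus could give such counts, and this was not tested.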
